A study of Mus musculus with 18 samples.

How the data were processed

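Substitutions were measured in a 679-base stretch of the reporter mOrangeSTOP, positions 45 to 723 of its coding sequence, in 18 libraries of genomic DNA from NIH-3T3 cells, a mouse fibroblast line. Each library came from cells transduced with the reporter, with a vector for AID fused to an estrogen receptor domain (AID-ER) or for its catalytically inactive form (AID-E58Q-ER), and with a vector that was empty (Control) or carried Ugi or UNG. Per the labels' protocols, cells were kept for 11 days in 1 µM OHT, the ligand of the fused receptor domain. The reporter was amplified for 25 cycles with Pfu Ultra, the product was sheared, and the library was amplified for 10 more cycles. The 6 combinations have 3 libraries each, numbered by experiment in the sample titles. The labels do not say whether the experiments were separate transductions, so p-values measure only the spread between these libraries, which may be partly technical.

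The deposited table gives, for each position and library, the number of reads, the count of base calls with a Phred quality over 20 and the count of each of the 12 possible substitutions among them, per the file headers. The submitters' processing notes name CASAVA 1.7, Novoalign 2.07.04 and SAMtools 0.1.11, without roles. The alignment settings are not given in the sources used here. The authors' fractions in the same table equalled the ratio of these counts within 1e-12 in all 18 libraries, so the counts alone were used. Positions are counted from the first base of the coding sequence. The reporter is a transgene, so no coordinates in the mouse genome apply, and no genome was used.

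The libraries held 24915866 to 95011754 calls that passed the quality limit, with a median coverage of 37304 to 141205 per position. At those medians, a count of 0 allows a frequency of up to 0.00804% in the shallowest library and 0.00212% in the deepest, taking 3 counts as the limit. In 9 libraries the reads at 13 to 15 positions between 45 and 59 stopped at nearly the same number (highest 499049 to 499939, against at most 253997 elsewhere), as a ceiling on the depth would leave them. No such setting is given in the sources used here, so coverage at those positions, and the totals of those libraries, may be too low. The calls come from PCR products without molecular identifiers, so such limits and the binomial intervals cover counting error only. Positions 700 to 704 had fewer than 1000 calls in at least 1 library and were left out, which left 674 positions, 426 of them C:G and 248 A:T base pairs. A further planned filter, on positions whose mean background over the 9 AID-E58Q libraries was over 1%, removed 0 positions, so keeping such positions changed nothing.

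Transitions (C>T, G>A, A>G, T>C) and transversions were counted separately at each position. edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) was fitted to all 18 libraries together with the logarithm of the coverage as the offset. Adjusted p-values are Benjamini-Hochberg values over the 674 positions, and the threshold was 0.05. The comparisons were AID over AID-E58Q in each arm and over the mean of the 3 arms, Ugi or UNG over Control within AID and within AID-E58Q, and the interactions of Ugi and of UNG with AID. Positions were grouped by sequence in classes that overlap: WRCY/RGYW (36 positions; W is A or T, R is A or G, Y is C or T, and the C or G is the position counted), its AGCT members (13), WRC/GYW not followed by Y (30), SYC/GRS (139; S is C or G), TC/GA (96), CpG (114), other C:G (131), WA/TW (74) and other A:T (174). The end positions 45 and 723 lack a full context and are in no class that needs it. The classes were tested with camera in limma 3.58.1 on transitions, with a preset correlation of 0.01 and with an estimated correlation. Camera sets the positions of a class against all other positions. Frequencies averaged over a class were compared on the log2 scale with exact two-sided permutation tests. With 3 libraries against 3, such a test cannot give a p below 0.1. Tests over the 3 arms together permuted libraries within arms and were adjusted over 10 tests. The transition share is the share of transitions in the excess over the mean of the arm's 3 AID-E58Q libraries, summed over transitions and transversions at C:G positions. It can pass 100% where the transversion excess is below 0.

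The positions named were fixed by a rule. In each arm they are the 10 with the largest fold change in transitions, and the 5 in transversions, among those past the threshold whose 3 AID libraries all lay on the same side of the 3 AID-E58Q libraries. For Ugi and UNG over Control they are the 5 largest in each direction. The stop codon and the AGCT bases were always included. The groups, tests, site classes, naming rule and most alternatives were chosen before the data were examined. A fold against a group whose libraries all had 0 calls is given as a lower bound, against 3 counts over the coverage of the whole group.

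The experiment number pairs libraries across groups. It was used as a block because the titles name it as an experiment, and this was decided before the fits were compared. Deviations from the group means correlated between libraries of the same experiment with a median r of 0.19 for transitions (0.03 to 0.63 over 45 pairs) and 0.50 for transversions (0.32 to 0.83). Between different experiments the medians were -0.23 and -0.47 over 90 pairs. The deviations sum to 0 within a group, so these negative values follow from the positive ones and add no evidence. Not every pair of the transitions passed 0.1, so the pairing rests on the labels. The design fixed beforehand has no block, and values with the block stand beside the results they change.

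The site test was tested on simulated data with known changes for the Control comparison. All 18 libraries were drawn from the Control AID-E58Q means and the real coverages, with the changes set in Control AID. Over 670 positions with transitions, the test recovered 10.0% of 2-fold, 52.0% of 4-fold, 93.9% of 8-fold and 100% of 16-fold changes, with 5 false calls. Over 669 positions with transversions it recovered 0%, 34.0%, 78.0% and 94.0%, with 2 false calls. The simulated libraries held no effect of experiment and no effect of AID in the other arms, so the rates may differ in the real data. Alternatives included DESeq2 1.42.0, limma on log2 frequencies, TMM factors, other coverage minimums, the ends removed, only the compared groups fitted, and each library left out in turn. Class values were also computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 as pooled frequencies and as medians, and figures were drawn with matplotlib 3.10.9.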

Results

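AID, activation-induced cytidine deaminase, turns cytosine into uracil in DNA. UNG, the uracil-DNA glycosylase, removes uracil, and Ugi is a protein inhibitor of UNG. The series asked how UNG activity shapes the substitutions that AID leaves in a reporter gene outside B cells. AID was set against the catalytically inactive AID-E58Q, which gives the background of PCR and sequencing, in 3 arms: Control (empty vector), Ugi and UNG. Each of the 6 groups had 3 libraries, from experiments 1 to 3. Frequencies are percentages of the calls at a position, or calls per 10000 averaged over the positions of a class. Between 24915866 and 95011754 calls passed the quality limit in a library, and in 9 libraries these totals may be held down by a ceiling on the depth at positions 45 to 59.

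In the Control arm, AID raised transitions at 17 of 674 positions, and all 17 were C:G base pairs. They lay mainly in WRCY/RGYW, the preferred sequence of AID, where 14 of 36 positions rose, and in its AGCT members, where 11 of 13 rose. Position 151, the C of an AGCT in codon 51, carried transitions in 1.93% ± 0.992 (SD, n = 3) of calls with AID and 0.0324% ± 0.0242 with AID-E58Q (log2 fold change 5.88, SE 0.97, adjusted p = 0.00247, edgeR). Averaged over WRCY/RGYW, transitions stood at 38.5 ± 23.0 per 10000 calls against 3.53 ± 1.37. Transversions rose at 23 positions, again all C:G, of which 20 were in WRCY/RGYW and 12 in AGCT.

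The 10 positions with the largest rise in transitions in the Control arm, 150, 151, 231, 232, 237, 268, 384, 385, 580 and 699, all lay in WRCY/RGYW, and 9 of them in AGCT. Position 699 rests on a coverage of at least 1046 calls, against at least 47748 at position 231. At position 231, the G of the in-frame stop codon, transitions made up 1.08% ± 0.581 with AID and 0.0311% ± 0.0156 with AID-E58Q (log2 fold change 5.10, SE 0.85, adjusted p = 0.00247, edgeR). Transversions rose most at positions 150, 151, 384, 699 and 708. At position 151 they made up 0.966% ± 0.440 with AID and 0.0259% ± 0.00409 with AID-E58Q (log2 fold change 5.22, SE 0.66, adjusted p = 1.96e-04, edgeR). At position 708 all 3 AID-E58Q libraries had 0 transversions, in 4701, 3382 and 16308 calls, and the AID libraries were at least 12.2-fold higher. Of these 5 positions, 150, 699 and 708 lost the call without AID-E58Q of experiment 3 (adjusted p = 0.0520, 0.125 and 0.0570), 150 and 699 without that of experiment 2 (both 0.0732) and 699 without AID of experiment 3 (0.0610, edgeR).

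Outside WRCY/RGYW, transitions in the Control arm rose at 1 of 30 positions of WRC/GYW not followed by Y and at 1 of 96 TC/GA positions. They rose at 0 of 139 SYC/GRS, 0 of 114 CpG and 0 of 131 other C:G positions, among 77 positions of all classes with an unadjusted p under 0.05. Adjusted over the list alone, 26 of 36 WRCY/RGYW, 13 of 13 AGCT and 5 of 30 positions of WRC/GYW not followed by Y rose, and 0 in the other classes. Of the WRCY/RGYW positions 38.9% rose, against 0.515% of the other 388 C:G positions (Fisher's exact test over positions, p = 7.33e-15), although positions are not independent replicates. Camera gave adjusted p = 1.04e-34 for WRCY/RGYW and adjusted p = 1.23e-31 for AGCT with the preset correlation, and adjusted p = 0.0479 and 0.0119 with an estimated correlation. WRC/GYW not followed by Y also stood above the other positions (adjusted p = 3.69e-09; adjusted p = 0.373 with an estimated correlation). SYC/GRS stood below them (adjusted p = 1.11e-04; adjusted p = 0.524 with an estimated correlation). With experiment as a block, transitions rose at 63 positions and transversions at 61, including 29 and 28 of WRCY/RGYW. Without AID-E58Q of experiment 1, 2 or 3, or AID of experiment 3, the transition count was 0, 2, 10 or 7, and the transversion count 14, 3, 3 or 14; without AID of experiment 2 the latter was 36. The transition and transversion counts were 0 and 0 without experiment 1, and 34 and 10 without experiment 3. They were 33 and 0 with only the compared groups fitted, and 59 and 39 by DESeq2. TMM factors gave 42 transitions. Without experiment 1 but with the block, transition calls stayed within 1.5 times of 17 and transversion calls numbered 44. Without AID-E58Q of experiment 1 the transitions at positions 151 and 231 had adjusted p = 0.0520 (edgeR).

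**Figure D1:**
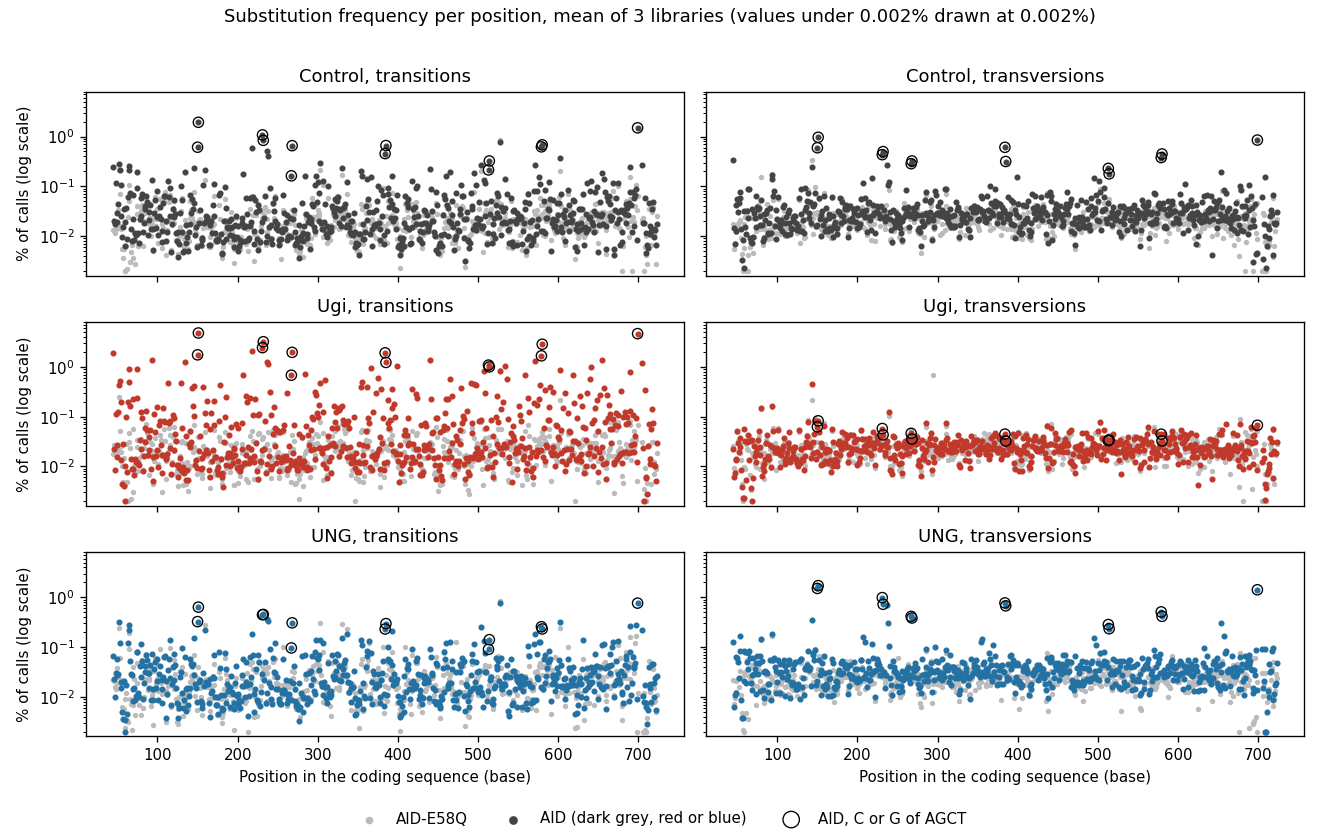
Mean substitution frequency of 3 libraries at each position (horizontal axis, base of the coding sequence; vertical axis, % of calls, log scale, values under 0.002% drawn at 0.002%), with AID in dark grey, red or blue, AID-E58Q in light grey and the C or G of AGCT circled. At position 151 transitions reached 1.93% with AID in Control and 4.82% in Ugi, while transversions stood at 0.966% in Control, 0.0827% in Ugi and 1.72% in UNG.

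With Ugi, AID raised transitions at 149 of 674 positions, all C:G. All 36 WRCY/RGYW positions rose, with a median fold change of 40.8, and so did all 13 AGCT positions, 24 of 30 positions of WRC/GYW not followed by Y, 57 of 131 other C:G positions, 22 of 96 TC/GA and 20 of 114 CpG positions. Of the SYC/GRS positions, known to be poor targets of AID, 3 of 139 rose. WRCY/RGYW transitions averaged 136 ± 132 per 10000 calls with AID (53.6 to 289 over the 3 libraries, the highest in experiment 3) and 3.74 ± 1.16 with AID-E58Q. Transversions did not pass the threshold at any position, and averaged 3.23 ± 0.604 per 10000 calls at WRCY/RGYW against 2.65 ± 0.554 with AID-E58Q.

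The 10 largest rises in transitions in the Ugi arm were at positions 45, 63, 150, 151, 231, 232, 384, 399, 534 and 699. At position 151 transitions made up 4.82% ± 4.10 with AID and 0.0391% ± 0.0169 with AID-E58Q (log2 fold change 6.93, SE 1.02, adjusted p = 2.03e-04, edgeR). At position 63, with a coverage of at least 1142 calls, the AID-E58Q libraries had 0 transitions in 1665, 1726 and 14823 calls, and the AID libraries were at least 11.9-fold higher; without AID-E58Q of experiment 3 the rise had adjusted p = 0.0527 (edgeR). Camera gave adjusted p = 2.35e-30 for WRCY/RGYW (adjusted p = 0.0528 with an estimated correlation, and 0.00610 with the block as well) and 1.32e-17 for AGCT (adjusted p = 0.0528, and 0.00610). Adjusted over the list alone, 28 of 30 positions of WRC/GYW not followed by Y rose, with 75 of 131 other C:G, 22 of 96 TC/GA, 19 of 114 CpG and 0 of 139 SYC/GRS positions. For transversions, the 0 calls of edgeR stand beside 4 positions with an unadjusted p under 0.05, 1 lower by DESeq2, 0 by limma and 1 lower with the block, at position 294. With the block, transitions rose at 208 positions and fell at 2, and without AID of experiment 3 or AID-E58Q of experiment 1 or 2 the count of 149 became 83, 99 or 96. It was 0 without experiment 1, 93 without experiment 3 and 70 with only the compared groups fitted. Without experiment 1 but with the block, it stayed within 1.5 times of 149.

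Ugi was then compared with Control among the AID libraries, which asks what blocking UNG changed. Transversions fell at 17 positions, all C:G, of which 15 were in WRCY/RGYW and 11 among the 13 AGCT positions. The largest falls were at positions 45, 151, 384, 580 and 708. At position 151 transversions fell from 0.966% ± 0.440 to 0.0827% ± 0.0132 (n = 3 each; log2 fold change -3.55, SE 0.60, adjusted p = 0.00826, edgeR). For transitions the WRCY/RGYW positions had a median log2 fold change of 2.08, but edgeR called 0 positions.

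Adjusted over the list alone, Ugi over Control passed in transitions at 19 of 36 WRCY/RGYW, 0 of 13 AGCT, 11 of 30 positions of WRC/GYW not followed by Y and 17 of 131 other C:G positions, and in transversions at 28 of 36 WRCY/RGYW and 13 of 13 AGCT positions. Beside the 0 transition calls of edgeR over all positions, 134 positions had an unadjusted p under 0.05; DESeq2 called 65 higher and 2 lower, limma called 0, and edgeR with the block called 112 higher and 1 lower. Averaged over C:G positions, Ugi over Control with AID was 1.65-, 2.16- and 4.02-fold in transitions within experiments 1, 2 and 3 (exact permutation p = 0.3 over the 6 libraries), and 0.599-, 0.742- and 0.316-fold in transversions (exact permutation p = 0.1, the smallest possible). The difference from the same comparison in AID-E58Q was tested as an interaction. It was past the threshold for transversions at 1 position, 151 (log2 difference -4.49, SE 0.81, adjusted p = 0.0220, edgeR; 16 positions lower with the block), and for transitions at 0, with 50 at an unadjusted p under 0.05 and 0 by DESeq2 or limma. Adjusted over the list alone, this interaction in transversions passed at 20 of 36 WRCY/RGYW and 12 of 13 AGCT positions, and in transitions at 0 of either. It gave 18 transversion calls by DESeq2 and 4 by limma, and 0 with only the compared groups fitted, with TMM factors or without experiment 1. Without experiment 1 but with the block it gave 6. Camera on transitions placed WRCY/RGYW higher with Ugi (adjusted p = 1.58e-12; adjusted p = 0.393 with an estimated correlation). With the block, 39 positions fell in transversions, and without Ugi AID of experiment 1, 2 or 3 or Control AID of experiment 1 or 3 the count of 17 became 0, 0, 1, 4 or 2. It was 0 without experiment 1, 2 without experiment 3, 0 with only the compared groups fitted, 9 without the first and last 25 positions and 30 by DESeq2. Without experiment 1 but with the block it was 33. At position 151 the fall had adjusted p = 0.0967, 0.0843 and 0.0559 without Ugi AID of experiment 1, 2 and 3 (edgeR), and the interaction was lost without any Control or Ugi library except Control AID of experiment 2 and Ugi AID-E58Q of experiment 3, where 2 positions passed. Transition calls rose to 42, 66 and 19 without Ugi AID of experiment 1 or 2 or Control AID of experiment 3, 25 without experiment 3 and 31 with TMM factors.

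With UNG added, AID raised transversions at 21 of 674 positions, all C:G. Of these, 15 were in WRCY/RGYW, 12 in AGCT and 3 in WRC/GYW not followed by Y. At position 151 transversions made up 1.72% ± 0.961 with AID and 0.0360% ± 0.00273 with AID-E58Q (n = 3 each; log2 fold change 5.58, SE 0.67, adjusted p = 9.77e-05, edgeR). WRCY/RGYW transversions averaged 34.1 ± 20.5 per 10000 calls against 2.38 ± 0.214, and transitions 18.96 ± 12.8 against 3.69 ± 1.30. No position passed the threshold in transitions.

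The 5 largest rises in transversions with UNG were at positions 150, 151, 231, 699 and 708. At position 708 the AID-E58Q libraries had 0 transversions in 2013, 1947 and 15687 calls, and the AID libraries were at least 6.0-fold higher. This call was lost without AID-E58Q of experiment 1, 2 or 3 or AID of experiment 3 (adjusted p = 0.0602, 0.0660, 0.371 or 0.0664, edgeR). Of the 21 positions, 16 were also among the 23 of the Control arm, where independent lists would share 0.717 (Fisher's exact test, p = 6.55e-23, from different libraries of the same experiments). Both lists lay mostly in WRCY/RGYW, which by itself makes them share positions, and positions are not independent replicates. The p-value thus does not show an overlap beyond that common site preference. For transitions, 44 positions had an unadjusted p under 0.05; DESeq2 called 22, limma 6, and edgeR with the block 28 higher and 2 lower, including 19 of WRCY/RGYW and 12 of AGCT. Adjusted over the list alone, 12 of 36 WRCY/RGYW and 13 of 13 AGCT positions rose in transitions. Camera gave adjusted p = 1.41e-23 for WRCY/RGYW (adjusted p = 0.147 with an estimated correlation, and 0.0165 with the block as well) and adjusted p = 2.08e-26 for AGCT (adjusted p = 0.0237 with an estimated correlation). With the block, 32 positions rose and 1 fell in transversions, and without AID-E58Q of experiment 1 or 2 the count of 21 became 11 and 11; without that of experiment 3, transition calls became 1. Transversion counts were 0 without experiment 1 and 11 with only the compared groups fitted. Transition counts were 18 without experiment 3, 14 with only the compared groups and 20 with TMM factors. Without experiment 1 but with the block, transversion calls stayed within 1.5 times of 21 and transition calls numbered 12.

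UNG over Control among the AID libraries passed the threshold at 0 positions for transitions and 0 for transversions. At AGCT the median log2 fold change was -1.15 in transitions and 0.55 in transversions. At unadjusted p under 0.05 there were 20 and 22 positions; DESeq2 called 0 and 1, limma 0 and 0, and edgeR with the block 5 lower in transitions (positions 45, 48, 54, 151 and 534) and 1 higher in transversions (position 369). Of these, position 151 is an AGCT base and positions 45 and 534 were also named by the rule in the Ugi arm. Positions 48, 54, 369 and 294 were named after their values were seen. Averaged over C:G positions the ratio was 0.696, 0.916 and 0.663 in transitions and 1.75, 1.13 and 1.23 in transversions within experiments 1, 2 and 3 (exact permutation p = 0.6 and 0.5). The UNG AID library behind the 1.75 had C>A and G>T calls raised at SYC/GRS (median 4.95 per 10000 calls). Camera placed WRCY/RGYW transitions lower with UNG (adjusted p = 1.51e-09; adjusted p = 0.738 with an estimated correlation). The interaction of UNG with AID was past the threshold at 0 positions for transitions and for transversions, with 12 and 5 at an unadjusted p under 0.05, 1 lower and 0 by DESeq2, and 0 by limma.

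The AID-E58Q libraries were compared between arms to ask whether Ugi or UNG changed substitutions without AID activity. Ugi over Control gave 0 calls by edgeR in transitions and in transversions (8 and 5 positions at an unadjusted p under 0.05; 0 and 1 by DESeq2, 0 by limma, and 0 and 1 with the block). UNG over Control gave 0 and 0 (9 and 1 positions at an unadjusted p under 0.05, 0 by the other tools and with the block). The transversion call with the block was position 294. Camera placed TC/GA and SYC/GRS transitions lower with Ugi in AID-E58Q (adjusted p = 8.06e-11 and 0.00703) and other A:T positions higher (adjusted p = 0.0192), each with adjusted p = 0.951 with an estimated correlation. Without AID-E58Q of experiment 3 in the Ugi or UNG arm, 1 position was called in Ugi transversions and 1 in UNG transitions.

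Over the 3 arms together, AID raised C:G transitions 2.98-fold (exact permutation p = 0.0005, adjusted 0.00250 over 10 tests) and C:G transversions 1.88-fold (exact permutation p = 0.00250, adjusted 0.00625). Transitions were higher with AID than with AID-E58Q of the same experiment in 9 of 9 pairs, by 2.49-, 2.06- and 3.10-fold in Control, 5.19-, 4.11- and 12.8-fold in Ugi and 1.49-, 1.47- and 1.92-fold in UNG. Transversions were 2.06-, 1.80- and 3.49-fold in Control, 1.06-, 0.930- and 1.12-fold in Ugi and 3.51-, 1.83- and 3.24-fold in UNG. Without position 294, where G294T stood at 0.935% and 1.08% in the Ugi AID-E58Q libraries of experiments 1 and 2, the Ugi values were 1.16-, 1.04- and 1.12-fold. By position, the mean of the 3 arms was higher at 130 positions in transitions (178 with the block) and at 33 in transversions (59 with the block). Without experiment 1 these counts were 43 and 0, and without experiment 3 the transversion count was 19. Without experiment 1 but with the block, the counts stayed within 1.5 times of 130 and 33. Taken as medians over positions, the rise in transversions had exact permutation p = 0.117. A median over C:G positions depends little on the 36 in WRCY/RGYW. The transition frequency at WRCY/RGYW relative to other C:G positions was 7.52 ± 1.84 in Control, 11.0 ± 1.01 in Ugi and 4.14 ± 1.89 in UNG with AID, against 1.21 ± 0.151, 1.41 ± 0.0293 and 1.08 ± 0.199 with AID-E58Q (5.57-fold, exact permutation p = 0.00025, the smallest possible; adjusted 0.00250). With the background included, this enrichment differed among the 3 AID groups (exact permutation p = 0.0250, adjusted 0.0417). C:G transitions (p = 0.1) and transversions (p = 0.0571, both exact permutation) did not pass. Without any library of Ugi AID, without Control AID of experiment 1 or without UNG AID of experiment 1 or 2, the enrichment did not pass either (exact permutation p = 0.0571 to 0.0786), nor did it without experiment 1 (0.267) or 3 (0.0667, the smallest possible), while without UNG AID of experiment 2 the transversions did (exact permutation p = 0.0143). Permuted within experiments, transitions and transversions both gave exact p = 0.0278. Because the enrichment includes the background, arms with fewer AID transitions lie nearer the AID-E58Q ratio. As class averages, the excess of transitions over AID-E58Q at WRCY/RGYW was 34.9 in Control, 133 in Ugi and 15.3 in UNG. At C:G positions outside WRCY/RGYW it was 1.96, 9.10 and 0.988. The difference in enrichment thus does not show that the site preference of AID differed between arms. None of the 10 class differences between arms in the effect of AID passed. The lowest was transversions in Ugi (exact permutation p = 0.0700, adjusted 0.700). AID and AID-E58Q labels were permuted within arms, so arrangements that swap an arm turn the difference into a sum. The effect of AID itself thus widens the permuted values, and the test cannot decide whether the arms differ.

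**Figure D2:**
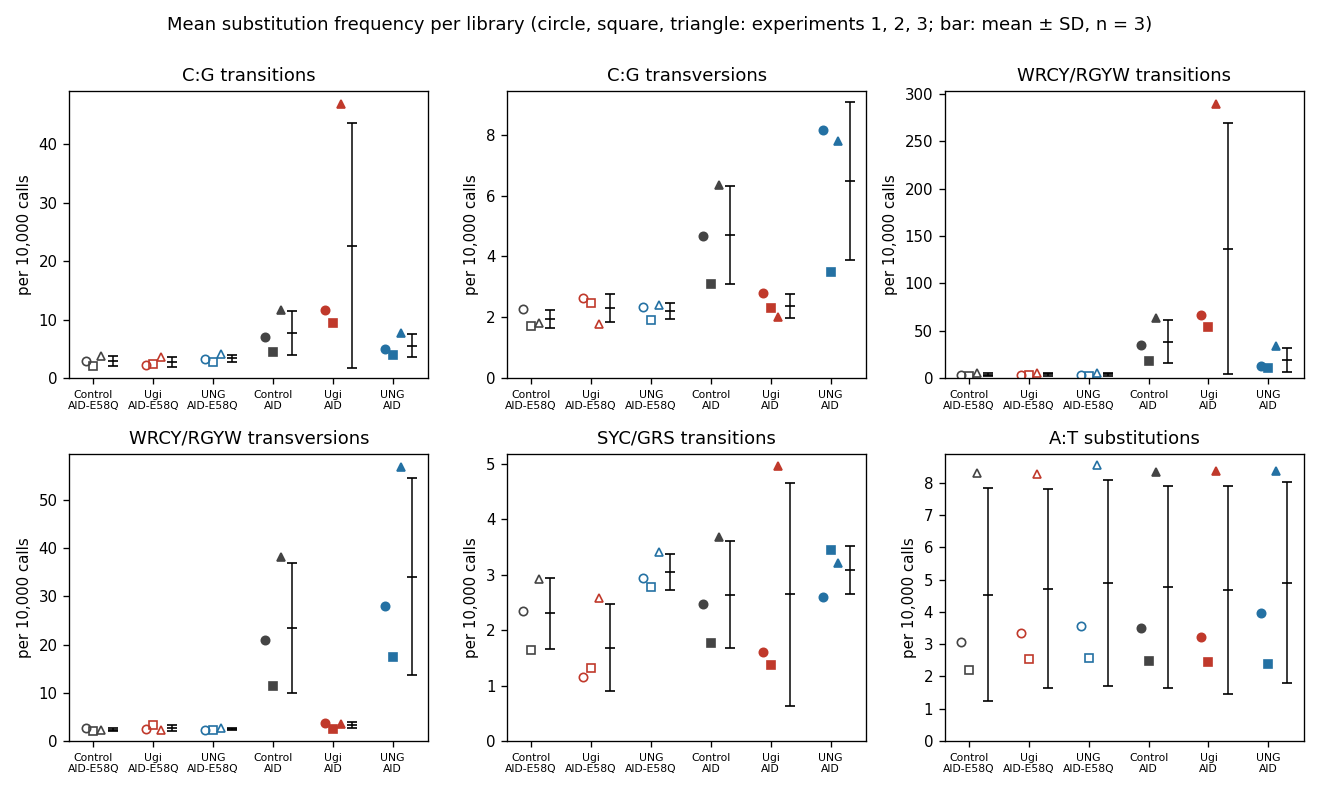
Mean substitution frequency of each library (vertical axis, per 10000 calls) by group (horizontal axis), with a symbol per experiment and bars for mean ± SD (n = 3). At WRCY/RGYW transitions averaged 38.5, 136 and 18.96 with AID in Control, Ugi and UNG, and transversions 23.4, 3.23 and 34.1.

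The makeup of the C:G excess over AID-E58Q separated the arms. Transitions were 60.9% ± 5.28 of it in Control, 98.4% ± 3.26 in Ugi and 33.0% ± 11.7 in UNG (SD, n = 3), and the 3 arms did not overlap (exact permutation p = 0.00357, the smallest possible; adjusted 0.00714). The UNG shares were 20.8%, 34.2% and 44.0% in experiments 1, 2 and 3; the library of experiment 1 also had raised C>A and G>T calls at SYC/GRS (median 4.95 per 10000 calls, at most 1.77 in the other libraries). Without that library the arms gave the same exact permutation p, and without experiment 1 p = 0.0667, the smallest possible with 2 libraries a group. Against the AID-E58Q library of the same experiment the shares were 63.1%, 100.1% and 35.7%. Each pair of arms gave exact permutation p = 0.1, the smallest for 3 against 3 libraries. Taken as medians over positions, the shares did not pass (exact permutation p = 0.454). Of the 426 C:G positions 36 are WRCY/RGYW, so a median depends little on them. The median log2 fold change of AID over AID-E58Q at C:G was 0.09 for Ugi transversions and 0.30 for UNG transitions. A share of such small rises cannot decide whether the arms differ. Over the 13 AGCT positions, the median frequency of C>G or G>C was 0.348% in Control, 0.0204% in Ugi and 0.495% in UNG with AID, and that of C>A or G>T was 0.0953%, 0.0238% and 0.0965%. With AID-E58Q the C>G or G>C median was 0.0117%, 0.0121% and 0.0120%, and the C>A or G>T median 0.0202%, 0.0224% and 0.0168%.

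**Figure D3:**
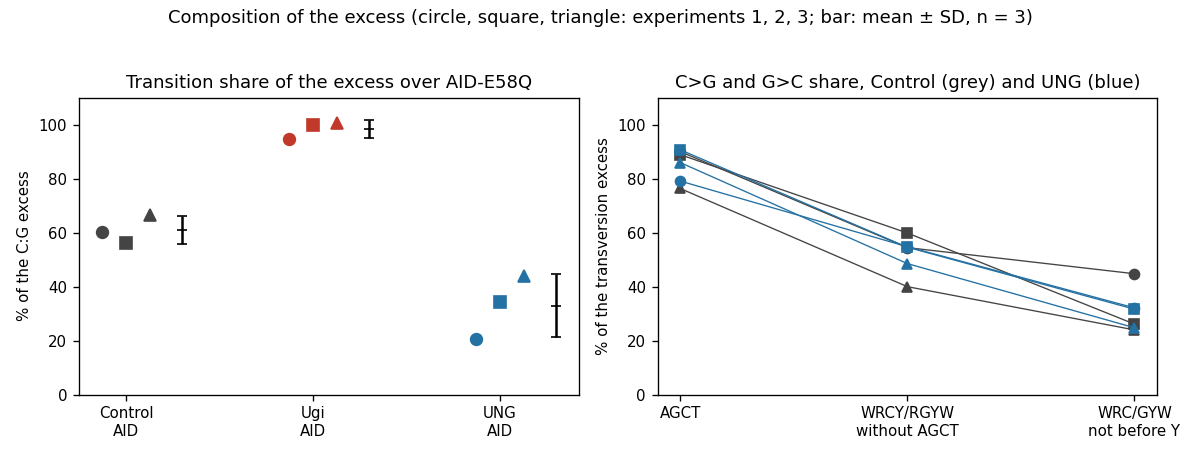
Left, transition share of the C:G excess over AID-E58Q (vertical axis, %) in the 3 AID groups; right, share of C>G and G>C in the transversion excess (vertical axis, %) at AGCT, other WRCY/RGYW and WRC/GYW not followed by Y, in Control (grey) and UNG (blue), with a symbol per experiment and bars for mean ± SD (n = 3). The transition share averages 60.9% in Control, 98.4% in Ugi and 33.0% in UNG.

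At the in-frame stop codon of the reporter, TAG at positions 229 to 231 (codon 77), substitutions of the G decide whether the codon codes for an amino acid. G231A leaves a stop codon (TAA), and it made up 1.08% ± 0.581 of calls with AID in Control, 2.45% ± 1.99 in Ugi and 0.448% ± 0.318 in UNG (n = 3), against 0.0311% to 0.0412% with AID-E58Q. G231C gives a tyrosine codon (TAC), and it made up 0.348% ± 0.344 in Control, 0.0211% ± 0.0109 in Ugi and 0.921% ± 0.484 in UNG, against 0.00764% to 0.0133% with AID-E58Q. G231T, also a tyrosine codon (TAT), stood at 0.0837% ± 0.0568, 0.0368% ± 0.0167 and 0.0691% ± 0.0658, against 0.0137% to 0.0229% with AID-E58Q. In experiment 2 it was lower with AID than with AID-E58Q in Control (0.0197% against 0.0254%) and UNG (0.00747% against 0.0105%). In experiment 3 it was lower in Ugi (0.0180% against 0.0190%), and in the other pairs of the same experiment it was higher with AID. Transversions at position 231 rose with AID in Control (log2 fold change 3.82, SE 0.77, adjusted p = 0.00840) and in UNG (5.25, SE 0.83, adjusted p = 9.76e-04, edgeR), but not in Ugi (0.71, SE 0.70, adjusted p = 0.999). They fell in Ugi compared with Control among AID libraries (log2 fold change -2.90, SE 0.74, adjusted p = 0.0445, edgeR). The interaction of Ugi with AID at this position had adjusted p = 0.236 and that of UNG adjusted p = 1.00 (edgeR). Without AID-E58Q of experiment 2 or 3 the rise in Control had adjusted p = 0.0732 or 0.0548, and without Ugi AID of experiment 1, 2 or 3 or Control AID of experiment 1 or 3 the fall in Ugi had adjusted p = 0.173, 0.229, 0.223, 0.0851 or 0.450 (edgeR). Transitions at position 231 had adjusted p = 0.0592 in UNG, and adjusted p = 1.44e-04 with the block (edgeR).

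**Figure D4:**
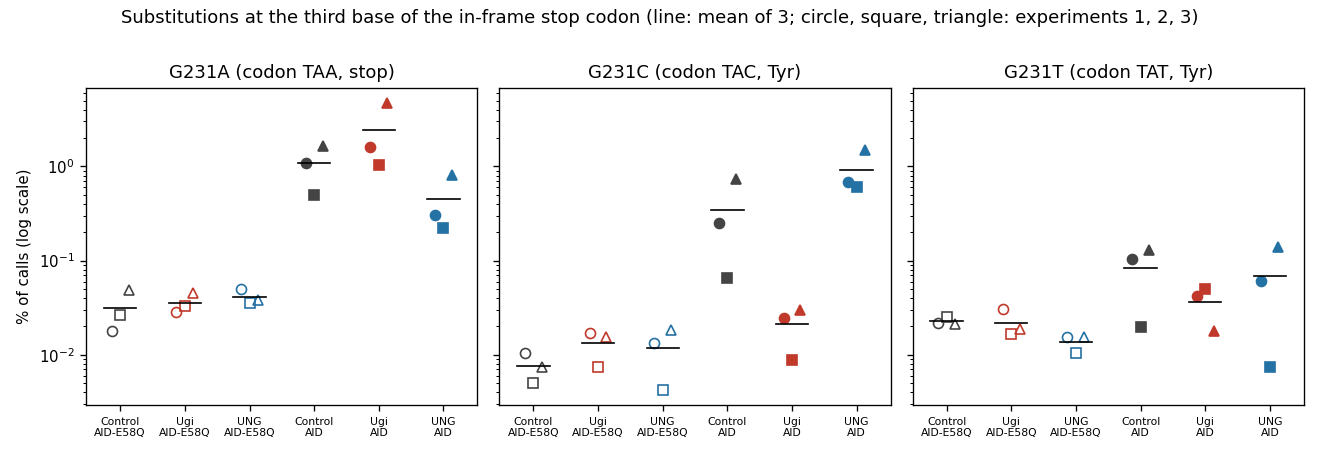
Frequency of the 3 substitutions at position 231 in each library (vertical axis, % of calls, log scale; horizontal axis, group), with a symbol per experiment and a line at the mean of 3. G231C averages 0.348% in Control, 0.0211% in Ugi and 0.921% in UNG with AID, and at most 0.0133% with AID-E58Q.

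At A:T base pairs, edgeR without the block called 0 of 248 positions in each of the 20 position counts, and over all settings tried 34 of 474 counts included A:T positions, at most 12. All A:T substitutions together averaged 4.78 ± 3.13, 4.68 ± 3.21 and 4.91 ± 3.12 per 10000 calls with AID in Control, Ugi and UNG, and 4.53 ± 3.31, 4.72 ± 3.09 and 4.90 ± 3.20 with AID-E58Q (1.02-fold over the 3 arms, exact permutation p = 0.917). Of the 74 WA/TW and 174 other A:T positions, 0 were called in transitions or adjusted over the list alone. At WA/TW, the context of A:T mutation in B cells, the means with AID were 4.92 ± 3.53, 4.66 ± 3.51 and 4.87 ± 3.46. The spread is between experiments: A>C averaged 4.45 per 10000 calls in the 6 libraries of experiment 3, against 0.736 and 0.497 in experiments 1 and 2, and T>G averaged 7.70 against 1.16 and 0.775. Within experiments 1, 2 and 3, AID over AID-E58Q at A:T was 1.15-, 1.12- and 1.00-fold in Control, 0.959-, 0.961- and 1.01-fold in Ugi and 1.12-, 0.917- and 0.981-fold in UNG. With the block, 1 to 2 A:T positions were called in 5 of the 20 position counts.

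The strand ratio of transitions, C>T at C positions over G>A at G positions of the coding strand, was 0.683 ± 0.0212 in Control, 0.844 ± 0.0377 in Ugi and 0.633 ± 0.133 in UNG with AID, against 0.531 ± 0.0570, 0.729 ± 0.0665 and 0.502 ± 0.0702 with AID-E58Q (n = 3 each). With the background included, the ratio was 1.23-fold higher with AID (exact permutation p = 0.00250, adjusted 0.00625). It was higher in 9 of 9 pairs of the same experiment, by 1.06- to 1.69-fold. Taken as medians over positions, the log2 difference was -0.01 (exact permutation p = 0.922), and without the 2 positions over 0.3% mean background it was 0.18 (exact permutation p = 0.0610). Without experiment 1 it was 0.23 and did not pass either (exact permutation p = 0.0556).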

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

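The tests of base quality across libraries were chosen after the low-quality calls were seen, while those of the relation to substitutions and of neighbouring A:T positions were set before their results. The interactions were planned.

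The effect of AID on transversions differed between Ugi and Control at 1 position, 151, the C of an AGCT in codon 51 (log2 difference -4.49, SE 0.81, adjusted p = 0.0220, edgeR). For the interaction in transitions, camera with the preset correlation set 7 site classes apart from the other positions with Ugi. Of these, WRCY/RGYW, WRC/GYW not followed by Y, AGCT, TC/GA and other C:G stood above the other positions, and WA/TW and other A:T below them. The median log2 interaction with Ugi was 0.05 at WA/TW and -0.13 at other A:T, against 2.03 at WRCY/RGYW. Standing below the other positions thus does not show that the effect of AID fell at A:T. With UNG, camera set 3 site classes apart, WRCY/RGYW, AGCT and WRC/GYW not followed by Y, all below the other positions. With an estimated correlation 0 of these 10 class results passed (adjusted p of at least 0.437 with Ugi and 0.933 with UNG). With the block as well, WA/TW and other A:T passed with Ugi, both below the other positions (adjusted p = 0.0417 and 0.00337), and 0 classes with UNG.

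Calls that failed the quality limit, not used in the comparisons, were more frequent at WRCY/RGYW with AID than with AID-E58Q. The difference was 0.162 percentage points in Control, 0.493 in Ugi and 0.0745 in UNG. Experiment 3 raised the Ugi value, with 0.913 points against 0.287 and 0.278 in experiments 1 and 2. At WRCY/RGYW such calls were higher in 9 of 9 pairs of the same experiment (mean 0.243 points, 0.0358 to 0.913, the highest in Ugi of experiment 3). They were also higher in 9 of 9 at A:T (mean 0.0529), 8 of 9 at SYC/GRS (0.0624) and 7 of 9 at WRC/GYW not followed by Y (0.0242). The 9 pairs come from 3 experiments and are not independent. A loss of quality over the whole library is argued against as the only source, since the WRCY/RGYW difference was over 2 times that at A:T in 8 of 9 pairs. It was over 2 times that at SYC/GRS in 8 of 9 as well. That count includes UNG of experiment 3, which passes by sign alone (0.0358 points at WRCY/RGYW, -0.0310 at SYC/GRS). A smaller library-wide part stays open. Whether calls that carry a substitution fail the limit more often could not be settled: over the WRCY/RGYW positions the median Spearman rho with the rise in substitutions was 0.177 (-0.309 to 0.452). At A:T positions within 3 bases of WRCY/RGYW the difference was larger than farther away in 8 of 9 pairs (0.0940 against 0.0310 points), which is consistent with substitutions lowering the quality of neighbouring bases.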

How the results depend on the processing

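The alternatives that left out experiment 1, experiment 3 or the UNG AID library of experiment 1, that removed positions over 0.3% mean background or position 294, or that added the block to the class tests were chosen after the results were seen; the others were chosen beforehand. Of 1022 alternative values of comparisons, 849 kept their direction and side of the threshold (counts within 1.5 times), 49 moved, 50 passed the threshold anew, 38 no longer passed and 36 reversed. The reversed values were A:T substitutions, C:G transversions of AID over AID-E58Q in Ugi, and the strand ratio taken as medians over positions. Of 3211 values at named positions, 2823 were the same, 125 passed anew and 263 no longer passed, and 0 reversed; of 270 class tests, 181 were the same, 1 passed anew and 88 no longer passed. Unless a value below shows it, the cause was not tested. The coverage of positions 699, 708 and 63 falls to 1046, 1947 and 1142 calls, which widens the counting error there.

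With experiment as a block, transition counts became 63 in Control, 30 in UNG, 113 for Ugi over Control and 5 for UNG over Control (both with AID). Transversion counts became 61 in Control, 1 in Ugi, 33 in UNG, 59 for the mean of the arms, 39 for Ugi over Control, 1 for UNG over Control, 1 for Ugi over Control in AID-E58Q and 16 for the Ugi interaction. The block changed the call of no other position count and moved none of them by more than 1.5 times. DESeq2 gave 59 transitions in Control, 22 in UNG, 67 for Ugi over Control and 1 for the UNG interaction, and 39 transversions in Control, 1 in Ugi, 30 for Ugi over Control, 1 for UNG over Control, 1 for Ugi over Control in AID-E58Q and 18 for the Ugi interaction. Limma gave 6 transitions in UNG and 4 transversions for the Ugi interaction. With only the compared groups fitted, the transition counts were 33 in Control, 70 in Ugi and 14 in UNG, and the transversion counts 0 in Control, 11 in UNG, 0 for Ugi over Control and 0 for the Ugi interaction. TMM factors gave 42 transitions in Control, 20 in UNG, 31 for Ugi over Control and 1 for UNG over Control, and 0 transversions for the Ugi interaction. Without the first and last 25 positions, 3 transitions and 9 transversions were called for Ugi over Control.

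Without experiment 1, transition counts were 0 in Control, 0 in Ugi and 43 for the mean of the arms, and transversion counts 0 in Control, 0 in UNG, 0 for the mean, 0 for Ugi over Control and 0 for the Ugi interaction. With the block as well, transition counts were 12 in UNG and 95 for Ugi over Control. Transversion counts were 44 in Control, 33 for Ugi over Control, 2 for UNG over Control and 6 for the Ugi interaction. The other counts with that block stayed within 1.5 times of those from all libraries without it. Without experiment 3, transition counts were 34 in Control, 93 in Ugi, 18 in UNG, 25 for Ugi over Control, 6 for UNG over Control, 2 and 1 for Ugi and UNG over Control in AID-E58Q and 2 for the UNG interaction. Transversion counts were then 10 in Control, 1 in Ugi, 19 for the mean, 2 for Ugi over Control and 1 for Ugi over Control in AID-E58Q. With the block as well, transitions gave 38 in Control, 18 in UNG, 35 for Ugi over Control, 5 for UNG over Control, 2 and 1 in AID-E58Q and 2 for the UNG interaction, and transversions 1 in Ugi, 1 for Ugi over Control in AID-E58Q and 6 for the Ugi interaction. Without UNG AID of experiment 1 and with the block, 25 transitions were called in UNG, and 37 transversions in UNG, 57 for the mean, 7 for UNG over Control and 1 for the UNG interaction.

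Each library left out in turn gave 0 to 19 transitions in Control, 83 to 192 in Ugi, 0 to 1 in UNG, 0 to 66 for Ugi over Control and 0 to 1 for UNG over Control in AID-E58Q. It gave 3 to 36 transversions in Control, 0 to 1 in Ugi, 11 to 25 in UNG, 0 to 17 for Ugi over Control, 0 to 1 for Ugi over Control in AID-E58Q and 0 to 2 for the Ugi interaction. The log2 fold change of A:T substitutions ran from -0.38 to 0.68 in Control, -0.56 to 0.47 in Ugi, -0.48 to 0.50 in UNG, -0.14 to 0.22 over the 3 arms, -0.57 to 0.45 for Ugi over Control and -0.45 to 0.54 for UNG over Control, and that of C:G transversions in Ugi from -0.12 to 0.16. Each lowest A:T value came without an AID library of experiment 3, where A>C and T>G were raised with AID and AID-E58Q alike. Within experiments, AID over AID-E58Q at A:T was 0.917- to 1.15-fold. The low ends thus carry the difference between experiments and do not show an effect of AID at A:T. The exact permutation p among arms ran from 0.00357 to 0.0786 for the WRCY/RGYW enrichment and from 0.0143 to 0.161 for C:G transversions.

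Among class values, medians over positions gave a log2 fold change of 0.34 for transversions over the 3 arms (exact permutation p = 0.117), -0.0081 for the strand ratio, -0.0089 for A:T in UNG and -0.0022 for A:T in UNG over Control, and exact permutation p = 0.454 for the transition share. A:T in UNG was -0.0034 from pooled frequencies, -0.0034 at a coverage of at least 10000, -0.030 without the ends and -0.077 without experiment 1, where A:T was also -0.0034 over the 3 arms and -0.031 for UNG over Control. Permuted within experiments as a block, the differences among arms had exact p = 0.0278 for transitions and 0.0278 for transversions. The strand ratio was 0.18 without positions over 0.3% mean background and 0.23 without experiment 1, and passed in neither (exact permutation p = 0.0610 and 0.0556). Without experiment 1 the enrichment and the transition share had exact permutation p = 0.267 and 0.0667, and without experiment 3 both had p = 0.0667 (the smallest possible with 2 libraries a group) and Ugi transversions a log2 fold change of -0.0099. With an estimated correlation 5 class tests passed, and 18 with the block as well.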

Other observations

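The tests of the C>G share, of the site preference and group of the raised C>A calls, and of other splits of the libraries were chosen after results were seen; the test at CCG and CGG was set before its result.

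The transversions that AID added differed with the sequence around the C. In WRCY/RGYW, C>G and G>C made up 76.9% ± 9.21 of the transversion excess in Control and 80.3% ± 4.94 in UNG (SD, n = 3), against 31.6% ± 11.4 and 29.5% ± 4.12 in WRC/GYW not followed by Y. The gap was 37.2 to 56.3 points in 6 of 6 libraries, which come from 3 experiments and share backgrounds within an arm. In 5 libraries C>A errors of the library are argued against as the source, since after the SYC/GRS level was subtracted the smallest gap was 30.6 points; in UNG AID of experiment 1 such errors stay open, since its C>A and G>T excess at SYC/GRS was 1.71 times the whole one at WRC/GYW not followed by Y (4.11 against 2.40 per 10000 calls). Much of the gap lay in AGCT: without it the WRCY/RGYW shares were 51.4% and 52.6%, with a gap of 9.68 to 33.7 points over the 6 libraries, so AGCT alone stays open, as does the hypothesis, found and tested on the same data, that the bases around the deaminated C set which transversion follows outside AGCT too (permutation of 23 and 30 positions without AGCT, p = 0.0432 over 6 libraries, 0.0355 without UNG AID of experiment 1 and 0.0818 without that of experiment 3).

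In the UNG AID library of experiment 1, C>A and G>T calls were raised across C:G positions, with a median of 4.95 per 10000 calls at SYC/GRS against 0.712 to 1.77 in the other libraries. AID acting at its preferred sequences is argued against as the source outside WRCY/RGYW, since the excess at WRC/GYW not followed by Y was 0.583 times that at SYC/GRS (95% bootstrap interval 0.357 to 0.869, added after the ratio was seen); at WRCY/RGYW it stays open, where the excess was 6.35 against 4.11 per 10000 calls, or 1.55 times (0.919 to 2.32). Added UNG together with AID stays open as well: 0 of the other UNG AID libraries lay above the highest AID-E58Q library (0.776 and 1.21 against 1.77), but this library was picked for standing apart, so that comparison restates the pattern. Guanine oxidised while the DNA was sheared stays open: the excess at CCG and CGG was 1.56 times that at other C:G positions outside WRC/GYW (95% bootstrap interval 1.22 to 1.97), which does not single out that source.

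G294T, in codon 98, was found in 0.935% (520 of 55589 calls; Clopper-Pearson 95% interval 0.857 to 1.02) and 1.08% (590 of 54760; 0.993 to 1.17) of calls in the Ugi AID-E58Q libraries of experiments 1 and 2, and in 0.00403% to 0.0452% in the other 16 libraries. It was chosen after its values were seen. No other substitution stood, in any AID-E58Q library, over 0.5% and over 10 times the median of the AID-E58Q libraries. Whether these 2 libraries share cells was not tested.

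Other splits of the same libraries were counted for each number of positions. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 17 and 149 transitions in Control and Ugi and 23, 21 and 17 transversions in Control, UNG and Ugi over Control, and in each of these 1 of 10 splits reached the count, with 0 as the highest other. Where the real count was 0, every split reaches it (10 of 10), so the splits decide nothing; the highest other was 88 for transitions in Ugi over Control with AID and 0 elsewhere. For the mean of the 3 arms, 1 of 100 drawn splits reached the 130 transitions (highest other 105), which argues against chance there. For its 33 transversions, 5 of 100 reached the count (highest other 231), so chance cannot be excluded without the block; the other splits as large put all libraries of an experiment on the same side. With the block 1 of 100 reached the 59 (highest other 56), which argues against chance there. For transitions and transversions alike, the drawn splits typically spread the experiments less evenly than the real one, so chance is not excluded. The splits for the interactions swapped AID and AID-E58Q within arms. Swapping 1 whole arm turns the difference between arms in the effect of AID into a sum, so these splits cannot decide on an interaction. For Ugi, 14 of 100 reached the 1 transversion (highest other 189), and with the block 7 of 100 reached the 16 (highest other 37). Chance stays open there. The 0 transitions of Ugi and of UNG and the 0 transversions of UNG are reached by every split (100 of 100; highest others 182, 31 and 156), which decides nothing. With the block the highest others were 194, 69 and 64 for the interactions with a real count of 0. Such high counts can carry the effect of AID itself, so they do not by themselves point to a structure of the libraries.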
